A study of Homo sapiens with 2 samples.

How the data were processed

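RNA-seq was available for 2 libraries of C4-2B cells, a castration-resistant subline derived from the human prostate cancer line LNCaP. One library came from C4-2B Con, the enzalutamide-sensitive line kept in medium with DMSO, and 1 from C4-2B ENZR, the resistant line kept in 20 µM enzalutamide, an antiandrogen. Both sample titles end in shC, which the labels do not explain, so both may carry a control shRNA. Total RNA was isolated with a column kit and sequenced as short single reads on an Illumina instrument, per the labels' protocols. The deposited table gave one signal value per gene and library, headed by the sample titles and described as TMM-normalized CPM, the reads of a gene per 1000000 reads of its library after TMM scaling, for 25343 rows with a gene symbol and a gene title. The submitters' processing notes name Bowtie2 2.1.0, RSEM 1.2.15, edgeR and the human build hg19, without saying which step each served, and the gene annotation and the use of strand are not given in the sources used here. The table held 0 further columns of sample values.

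The deposited values were not counts, but every value in a column was a whole multiple of 1 step, so whole reads per gene were recovered. RSEM gives estimated counts in which reads that map to several genes are shared out, so these whole reads may be rounded estimates. The share of values within 0.01 reads of a whole number was 100% in each library. The recovered total was 21024484 reads for Con and 23479051 for ENZR, and 1 read was worth 0.0490 CPM and 0.0404 CPM. The columns summed to 1030021 and 949450 CPM, which implies scaling factors of 0.971 and 1.05 if no rows were dropped before deposit. The product of these implied factors was 1.02 and not 1, so the authors' factors were not computed on these 2 libraries and these genes alone. With 1 library per group, edgeR's quasi-likelihood test has no residual degrees of freedom, so no count test of the conditions was run and no p-value is given. In its place, each ratio of 2 read counts received an exact 95% binomial interval (Clopper-Pearson). These intervals, and the floor of 3 counts used where a library had 0 reads (0.147 CPM in Con and 0.121 CPM in ENZR), cover counting error only and say nothing on variation between cultures or on how shared reads were assigned. The interval excluded a ratio of 1 for 9825 of the genes kept, which compares these 2 libraries and not the conditions.

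The main measure was the log2 ratio of ENZR over Con after adding a pseudocount of 1 CPM, computed for the 13803 genes whose mean over both libraries was 1 CPM or more. This log2 ratio understates the change of genes with low values, so folds in the text are plain CPM ratios, and counts of genes past 2-fold or 4-fold use the log2 ratio. In the text, "counting interval" stands for the exact 95% interval of the plain ratio. The table held 28 symbols that a spreadsheet had turned into dates, and 2 such symbols each stood for a pair of genes, which were told apart by the gene titles.

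Before the data were examined, 51 gene lists and the rule for named genes were fixed. The named genes are the 10 highest and 10 lowest log2 ratios among genes with a mean of 10 CPM or more, and 16 genes of the androgen axis, neuroendocrine state and proliferation whatever their values. To these the rule adds, from a list that stands apart, the 4 members with the largest change in its direction and the largest opposite member if it reached 2-fold, and from every other list up to 2 members past 2-fold. XIST and Y-linked genes are never named. Some genes that the rule takes, and 1 of the lists, are not reported here. For each of the 48 lists with 5 or more measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart at or under percentile 2.5 or at or over percentile 97.5. Over 48 lists, genes drawn at random give 2.4 such lists. Genes of a list can vary together between cultures, so more may stand apart between 2 cultures of 1 condition, and how many is unknown. The interval given with a list's median is the exact 95% interval over its members, which are not replicates. With members at 0 reads set to their bound against the floor, the median of 0 lists changed.

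The calculation was tested on simulated reads drawn from the real means and library sizes of 13815 genes. Of 50 genes made 3-fold higher, 94% passed 2-fold, and of 50 made 3-fold lower, 92% did. At 6-fold the shares were 100% and 98%. The counting interval held the true ratio for 95.5% of the 13615 unchanged genes and for 92% or more of the genes of each fold size. Of 100 random lists of 20 genes drawn from the 13803 real genes, 6 stood apart, and 98 of 100 did so after a shift of 0.5 in log2.

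Other settings, chosen beforehand, changed the pseudocount, the filter, the scaling, the treatment of abundant genes and repeated symbols, the matching of random lists and the summary of a list, and required the whole counting interval past the threshold. A further 4 settings were added after the data had been seen. These were subtraction of the median of transcript length and GC classes, subtraction of the median of neighbouring genes, use of list members held by no other list, and TMM factors recomputed on these 2 libraries. Transcript length and GC came from GENCODE 29 and were found for 96.6% of the kept genes. Chromosomes and neighbours came from RefSeq on GRCh38.p14, in which 97.4% of the kept genes were placed. This is another build than the authors' hg19, so no coordinates are given. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and TMM factors were recomputed with edgeR 4.0.16 in R 4.3.3.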

Results

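Gene expression was measured in enzalutamide-sensitive C4-2B Con cells (n = 1 library, 21024484 reads in genes) and enzalutamide-resistant C4-2B ENZR cells (n = 1 library, 23479051 reads). A mean of 1 CPM or more was reached by 13803 genes, and over these the log2 values of the 2 libraries had a Pearson correlation across genes of 0.932. The 10 most abundant genes took 4.57% of the Con total and 4.38% of the ENZR total. No value has a replicate, so the differences below describe 2 libraries, and the spread between cultures is unknown.

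The comparison asks how the transcriptome of cells kept in enzalutamide differs from that of their sensitive counterparts. KLK3, which encodes prostate-specific antigen and is a classical androgen-induced gene, stood at 1428 CPM in Con and 3.72 CPM in ENZR, 384-fold lower (counting interval 313 to 476). FASN, the fatty acid synthase, was 3.04-fold lower, and IGF1R, the insulin-like growth factor receptor, was 19.4-fold lower. HGF, the ligand of the MET receptor, rested on 2 reads in Con and 1268 in ENZR, a ratio of 523 with a counting interval of 145 to 4330.

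Among all measured genes, 923 were at least 2-fold higher in ENZR and 641 at least 2-fold lower, and 263 and 160 passed 4-fold. The counts depend on the pseudocount: with 5 CPM in place of 1 CPM, 447 genes were higher and 371 lower at 2-fold. When the authors' TMM scaling was undone, the median log2 ratio of all genes moved from -0.006 to 0.102. The direction of log2 ratios that lie below 0 by about that much or less thus rests on the scaling. Small ratios above 0 kept their direction in that setting, but their size rests on the scaling too. Each list median said below to cross 0 with the TMM scaling undone did so too with the 10 most abundant genes left out, except for glycolysis and heat shock genes. The medians of other nuclear receptors and of stem cell, unfolded protein response, lysosome and JAK-STAT3 genes also crossed 0 with upper quartile scaling.

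Among genes with a mean of 10 CPM or more, the highest log2 ratio belonged to KCNJ3, a subunit of an inwardly rectifying potassium channel, at 0.931 CPM in Con and 315 CPM in ENZR, a ratio of 338 (216 to 562). TLL1, a tolloid-like metalloprotease, had 3 reads in Con and 89.0 CPM in ENZR, a ratio of 606 (207 to 2940). SEMA6A, a transmembrane semaphorin, was 123-fold higher, TENM2, a teneurin of neuronal adhesion, 119.9-fold and LRRN1, a leucine-rich repeat membrane protein, 52.3-fold. FSTL5, a follistatin-like protein, had 3 reads in Con and 1023 in ENZR, a ratio of 282 (96.0 to 1370). The other members of the top 10 besides HGF were germ cell genes: VCX (1.52 CPM and 292 CPM), SSX2 (0.441 CPM and 75.7 CPM) and VCX3A (3 reads and 1042 reads, ratio 287, 97.8 to 1390). VCX, VCX3A and SSX2 have near-identical copies on the X chromosome, so the assignment of reads among the copies is uncertain.

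Among the named genes, the lowest log2 ratio after KLK3 belonged to GULP1, an adaptor of phagocytic engulfment, with 130 CPM in Con and 0 reads in ENZR, at least 1070-fold lower against the floor of 3 counts. PTGFR, the prostaglandin F receptor, had 1710 reads in Con and 2 in ENZR, and its ratio of Con over ENZR, 1036, had a counting interval of 286 to 8560. PCDH7, a protocadherin, was 175-fold lower, ST6GALNAC1, a sialyltransferase, 322-fold (163 to 747) and TM4SF1, a surface protein of the tetraspanin type, 165-fold. ACADL, a mitochondrial long-chain acyl-CoA dehydrogenase, was 220-fold lower (93.9 to 679). H2AFJ, an H2A histone variant, was 37.6-fold lower and ELOVL7, a fatty acid elongase, 23.9-fold.

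**Figure D1:**
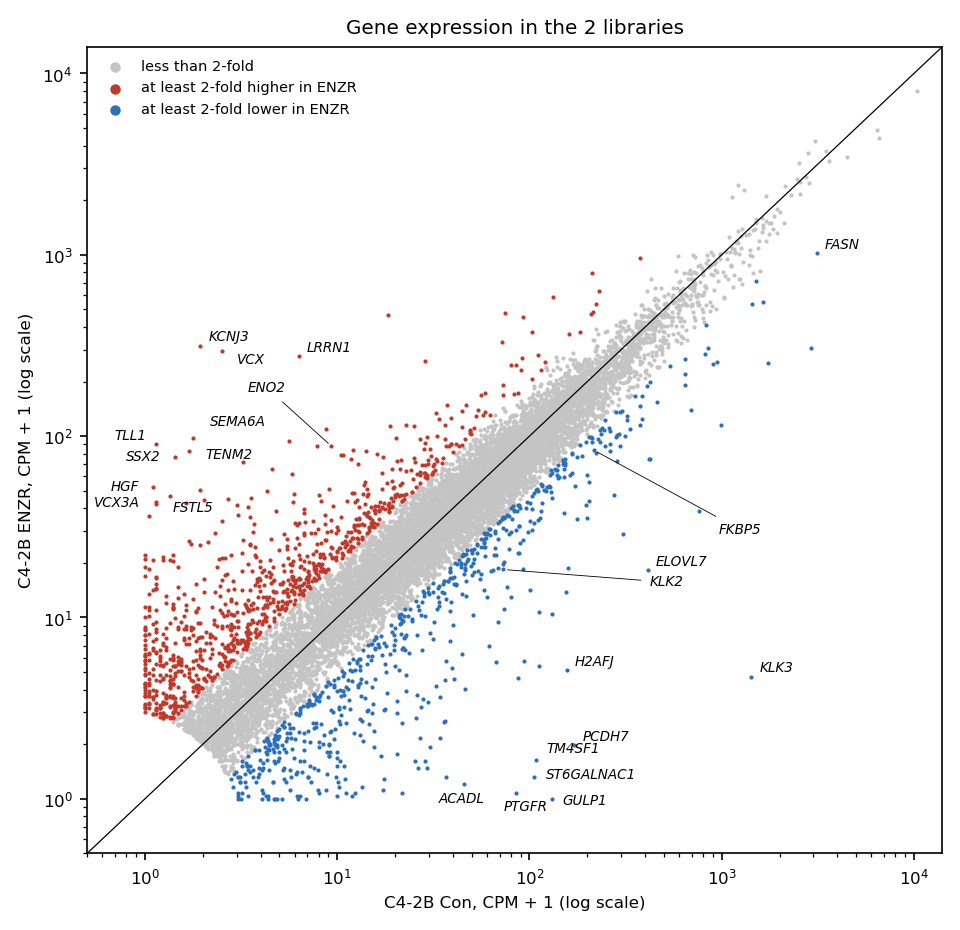
Each point is a gene, with its CPM + 1 in C4-2B Con on the x axis and in C4-2B ENZR on the y axis, both on log scales, with 1 library per group and the line of equal values in black. KLK3 (1428 CPM and 3.72 CPM) lies far below the line among abundant genes, while KCNJ3 (0.931 CPM and 315 CPM) lies far above it.

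Genes induced by androgens were lower in ENZR as a group. Of the 34 measured members of the androgen response list, 30 were lower, 14 of them at least 2-fold, and the median log2 ratio was -0.82 (-1.60 to -0.64), below each of the 10000 random lists. KLK2, a kallikrein beside KLK3, was 4.15-fold lower (72.2 CPM and 17.4 CPM), and FKBP5, a chaperone of steroid receptors, 2.60-fold lower. ABCC4, a transporter of cyclic nucleotides, was 10.9-fold lower, FAM105A 9.95-fold and GNMT, a glycine methyltransferase, 6.41-fold. ABCC4 lies on chromosome 13, whose genes had a median log2 ratio of -0.54. TMPRSS2, a serine protease gene, was lower by a smaller ratio of 1.52 (115 CPM and 75.6 CPM). ACPP, prostatic acid phosphatase, went against the list at 11.6 CPM in Con and 43.5 CPM in ENZR, 3.74-fold higher.

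Genes that androgens repress had a median of 0.47 at percentile 96.36 and did not stand apart in the main setting. They did as higher with a pseudocount of 5 CPM (0.39), without the filter on low values (0.89), with length and GC classes subtracted (0.57) and by the mean of the members (0.90). Within that list OPRK1, an opioid receptor, was 33.2-fold higher (20.0 to 59.8), and AKR1C3, an enzyme that makes testosterone from weaker androgens, had 0 reads in Con and 81 in ENZR, at least 22.3-fold higher at a level of 3.28 CPM. Of the 9 measured members of the list, 6 were above 0 and 3 below, among them UGT2B17 at 2.19-fold lower. AKR1C1 had 1 read and 66 reads, a ratio of 54.5 (9.44 to 2180). The AKR1C genes are close in sequence, so their split is uncertain.

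Steroid metabolism as a list did not stand apart (median -0.08, percentile 20.04, and 0.03 when the TMM scaling was undone), and neither did the UDP-glucuronosyltransferases (median -0.33, percentile 7.76). UGT2B15 was 1.42-fold higher and UGT2B17 2.19-fold lower, UGT2B28 was 8.08-fold lower (3.98 to 18.5), and UGT8 2.48-fold lower. The UGT2B genes share sequence, so these values are uncertain. The glucocorticoid receptor NR3C1 had 1 read in Con and 7 in ENZR, a ratio of 5.78 with a counting interval of 0.742 to 260. Glucocorticoid response genes were lower, with a median of -0.42 (-0.93 to 0.10) at percentile 0.23 and 12 of 16 members below 0. ZBTB16 was 7.49-fold lower, S100P 4.85-fold and HSD11B2 1.95-fold, FKBP5 belongs to this list too, and the clock gene PER1 was 2.06-fold higher. The other nuclear receptors had a median of -0.02, which became 0.10 with the TMM scaling undone, and their extremes were NR2F1 (7.56-fold lower) and PPARG (12.5-fold higher, 8.01 to 20.4).

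Lipid synthesis genes were lower in ENZR. The fatty acid synthesis list had a median of -0.72 (-1.35 to -0.07) and the cholesterol synthesis list -0.62 (-0.71 to -0.12), each below all 10000 random lists, with 18 of 22 and 18 of 23 members below 0. SREBF1, the transcription factor that drives fatty acid synthesis, was at 944 CPM in Con and 256 CPM in ENZR, 3.68-fold lower, FASN at 3119 CPM and 1026 CPM, and ACSL1, an acyl-CoA synthetase, was 5.68-fold lower. INSIG1, the sterol-regulated retention protein of the SREBP pathway, was 3.29-fold lower, FDFT1, squalene synthase, 3.02-fold, STARD4, a sterol carrier, 6.66-fold, and MSMO1 2.01-fold. SCD5, a stearoyl-CoA desaturase, was 3.80-fold higher against its list.

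Genes of amino acid supply under the transcription factor ATF4 were also lower, with a median of -0.54 (-0.81 to -0.29), 26 of 31 members below 0 and no random list as low. SLC7A11, the cystine transporter, was 2.82-fold lower, SLC7A1, the arginine transporter, 2.41-fold, the pseudokinase TRIB3 2.37-fold and the secreted factor GDF15 5.30-fold. The unfolded protein response (median -0.01, and 0.11 with the TMM scaling undone), heat shock genes (-0.11, and 0.01) and NRF2 genes (0.05) did not stand apart. GSTM2, a glutathione transferase, had 3 reads in Con and 385 in ENZR, a ratio of 106 (36.0 to 516), while SLC7A11, which is on the NRF2 list too, was lower.

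**Figure D2:**
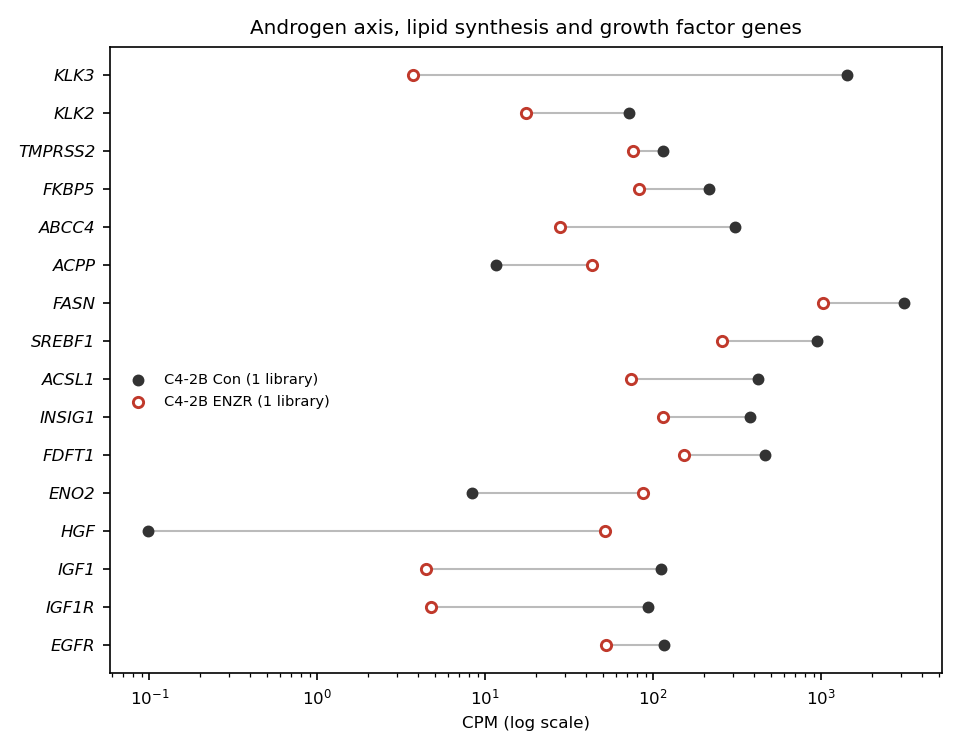
CPM on a log scale (x axis) of 16 genes (y axis) in C4-2B Con (filled) and C4-2B ENZR (open), with 1 library per group and a line joining the values of a gene. ACPP, ENO2 and HGF are higher in ENZR, and the other genes are lower, from 1428 CPM to 3.72 CPM for KLK3.

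Of 22 measured receptor tyrosine kinases and ligands, 3 were at least 2-fold higher, 6 at least 2-fold lower and 13 in between. IGF1 was 25.4-fold lower (112 CPM and 4.41 CPM) and its receptor IGF1R 19.4-fold lower (92.6 CPM and 4.77 CPM). EGF was 7.84-fold lower, FGFR3 8.33-fold and EGFR 2.20-fold, whereas HGF was among the 10 highest log2 ratios. The list had a median of -0.24 (-1.12 to 0.20) at percentile 1.75, and this place was lost without the filter on low values (median 0.0). Feedback genes of the MAPK pathway had a median of 0.05, but of -0.97 at percentile 0.01 over the members held by no other list. Of its 15 measured members, 4 were at least 2-fold lower, with PHLDA1 8.03-fold and DUSP4 10.6-fold, and 2 at least 2-fold higher, DUSP5 (2.61-fold) and ETV4 (12 reads and 162 reads, ratio 11.14, 6.21 to 22), both named after their values were seen. In the PI3K list (median -0.22, percentile 4.12), INPP4B, a phosphoinositide phosphatase, had 232 reads in Con and 2 in ENZR, a ratio of Con over ENZR of 140.5 (38.5 to 1170), and FOXO1 was 2.55-fold lower. SOCS2, a suppressor of cytokine signalling, was 10.1-fold lower in the JAK-STAT3 list, whose median was -0.02, or 0.09 with the TMM scaling undone.

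Semaphorins and their receptors were higher, with a median of 0.73 (0.31 to 2.47), 15 of 18 members above 0 and no random list as high. Besides SEMA6A, the receptors PLXND1 and NRP1 were 13.9-fold and 6.23-fold higher, and SEMA6D had 1 read in Con and 259 in ENZR, a ratio of 214 (38.0 to 8480). The WNT list stood apart at percentile 97.57 with a median of 0.25 (-0.20 to 1.36). WNT5A, a non-canonical ligand, was 9.49-fold higher, LEF1, a transcription factor of the pathway, 5.56-fold, the antagonist SFRP1 26-fold (9.91 to 96.9), and ROR2, a receptor for WNT5A, had 2 reads and 104 reads, a ratio of 42.9 (11.6 to 359). WNT10A was 4.54-fold lower. Notch genes (median -0.17) held HES6 at 6.56-fold lower and NOTCH3 at 2.61-fold higher. Hedgehog and TGF-beta/BMP genes (median 0.07) held ID1 at 6.32-fold higher and BMPR1B, a BMP receptor, with 206 reads in Con and 2 in ENZR, a ratio of Con over ENZR of 125 (34.1 to 1040).

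Interferon-stimulated genes were higher in ENZR. Of 23 measured members, 20 were higher, 10 of them at least 2-fold, and the median was 0.90 (0.41 to 1.25), above all random lists. IFIH1, a sensor of double-stranded RNA, was 6.82-fold higher (5.68 CPM and 38.8 CPM), IFIT1 6.83-fold, IFIT2 9.33-fold (4.89 to 20.0), and OASL had 3 reads and 72 reads, a ratio of 19.8 (6.51 to 98.3). BST2, which encodes tetherin and is itself interferon-inducible, was 22.2-fold lower (26.01 CPM and 1.17 CPM). Antigen presentation genes had a median of 0.32 (0.25 to 0.88) with 13 of 14 members higher, among them the immunoproteasome subunit PSMB8 (12.5-fold, 6.14 to 29.6), the peptide transporter TAP1 (2.81-fold), HLA-B (1.87-fold) and B2M (1.73-fold). NF-kB and cytokine genes had a median of 0.69 (-0.09 to 1.32), above all random lists. TNFAIP2 was 3.74-fold higher, ACKR3, a chemokine receptor, 2.60-fold, RELB 3.97-fold (2.30 to 7.29), and CCL20 had 2 reads and 63 reads, a ratio of 26 (6.91 to 219).

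**Figure D3:**
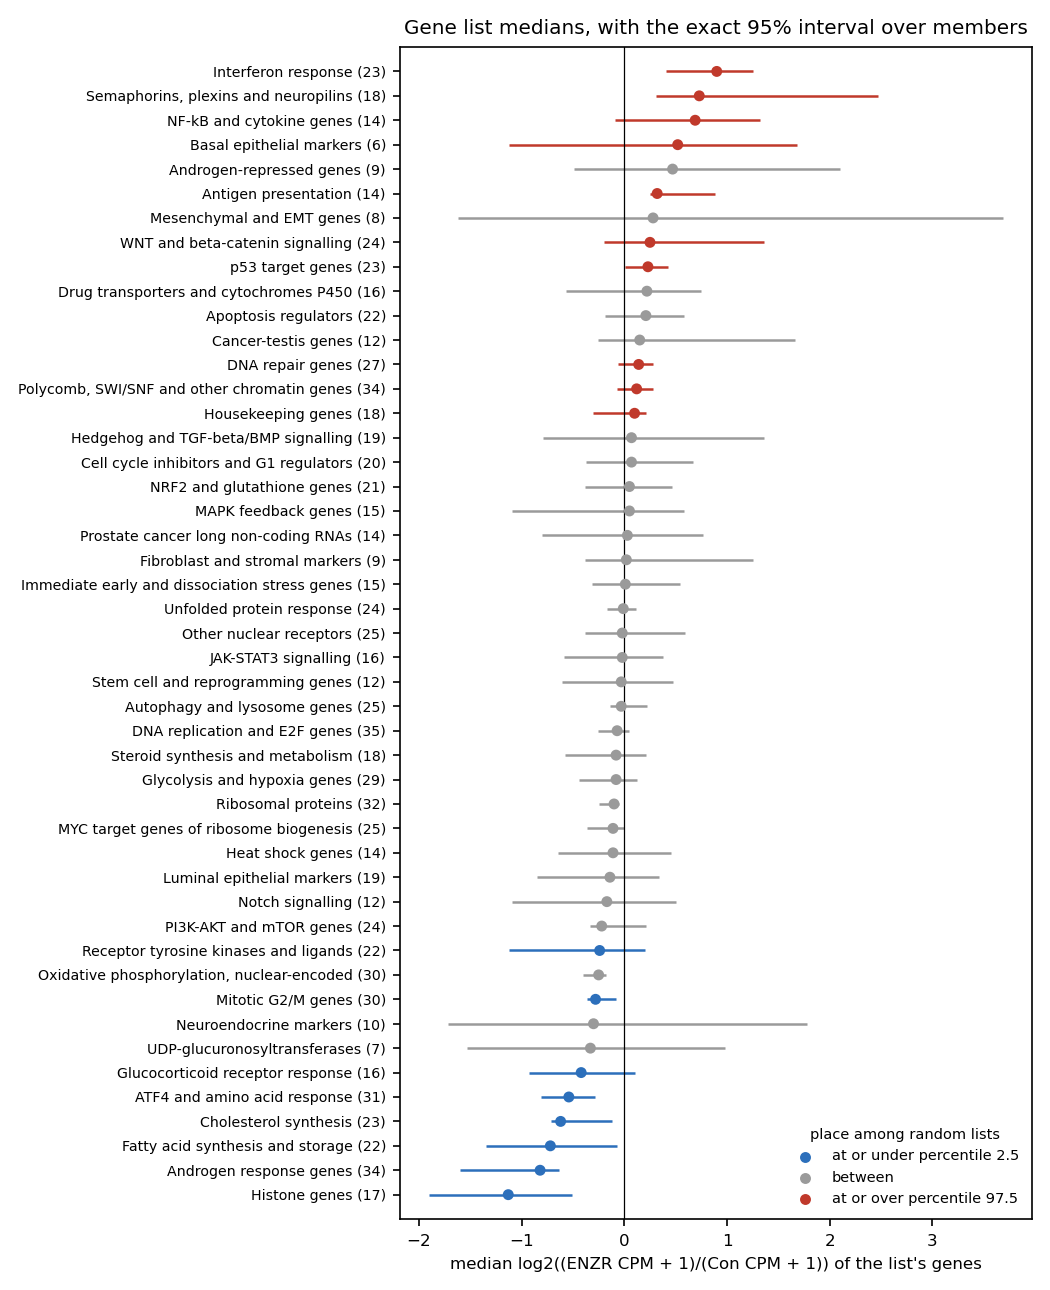
Median log2 ratio of ENZR over Con (x axis, pseudocount 1 CPM) for 47 gene lists (y axis, measured members in parentheses), with the exact 95% interval over members as a line and colour for the place among random lists. Histone genes (-1.13) and androgen response genes (-0.82) have the lowest medians, and interferon response genes (0.90) the highest.

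The proliferation marker MKI67 was at 350.5 CPM in Con and 346 CPM in ENZR, a ratio of 0.988 (0.958 to 1.02), which lay above 1 with the TMM scaling undone, with upper quartile scaling and with the 10 most abundant genes left out. Mitotic genes had a small negative median of -0.28 (-0.36 to -0.08) at percentile 1.57, with CCNA2, cyclin A, 1.92-fold lower and HMMR, CDC25C and KIF20A 1.65-fold, 1.68-fold and 1.63-fold lower. Replication genes did not stand apart (median -0.07, and 0.05 with the TMM scaling undone). Among G1 regulators (median 0.07), the antiproliferative gene BTG1 was 6.45-fold higher, and CCND2, a D-type cyclin, had 1 read and 226 reads, a ratio of 187 (33.1 to 7400), and of 20 measured members 4 were at least 2-fold higher and 1 at least 2-fold lower. DNA repair genes had a median of 0.14 (-0.06 to 0.28) at percentile 98.39, with BLM 1.44-fold and BRCA1 1.37-fold higher, and BARD1 was 2.25-fold lower. The p53 targets had a median of 0.23 (0.01 to 0.43) at percentile 98.27, with SESN1 2.46-fold, BTG2 2.37-fold, TP53I3 2.19-fold and FDXR 1.59-fold higher. GDF15 went against them.

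Histone genes had the lowest median of all lists, -1.13 (-1.90 to -0.51), with 15 of 17 members lower and no random list as low. After H2AFJ came HIST1H2BK (204 CPM and 42.9 CPM, 4.75-fold lower), HIST1H1C, a linker histone, 4.0-fold lower, and HIST1H2BJ 6.02-fold lower (4.07 to 9.16). H1F0, a linker histone of non-dividing cells, was 2.27-fold higher. Histone genes resemble each other in sequence, so the values of single members are uncertain. The chromatin regulators had a median of 0.12 (-0.07 to 0.28) at percentile 98.70, led by SMARCD3 (2.42-fold), TET1 (2.61-fold), CBX7 (1.67-fold) and KMT2D (1.58-fold).

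Neuroendocrine markers did not stand apart in the main setting (median -0.30, percentile 3.16), but did as lower with a pseudocount of 5 CPM (-0.22), a mean of 5 CPM or more (-0.58) or the neighbours' median subtracted (-0.47). Of 10 measured members, 2 were at least 2-fold higher and 3 at least 2-fold lower. ENO2, neuron-specific enolase, was 10.5-fold higher (8.33 CPM and 87.1 CPM), whereas VGF was 4.47-fold lower. The other higher member, NCAM1, named after its values were seen, had 3 reads and 73 reads, a ratio of 20.1 (6.61 to 99.6). SYP, synaptophysin, was at 1.67 CPM and 1.29 CPM with a counting interval of the ratio from 0.464 to 1.30, and CHGA, chromogranin A, had 0 and 3 reads, too few for a fold. Among monoamine genes, a list with 4 measured members, DDC, which is on the neuroendocrine list too, was 3.40-fold lower. Basal markers stood apart on 6 members (median 0.52, percentile 97.82), of which 3 were above 0 and 3 below. TRIM29 was 6.04-fold (3.57 to 10.9), LAMB3 11.1-fold (4.11 to 42.4) and ITGB4 2.58-fold higher, and EGFR was lower. TRIM29 and LAMB3 had only 16 and 4 reads in Con. The list's place was lost with a pseudocount of 5 CPM (median 0.13). Luminal markers had a median of -0.14, with CLDN3 3.13-fold lower and CD24 5.08-fold higher.

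Mesenchymal genes had a median of 0.28 (percentile 89.28). Of 8 measured members, 6 were above 0 and 2 below, with 2 at least 2-fold higher and 1 at least 2-fold lower. FN1, named after its values were seen, was 2.77-fold higher (228.6 CPM and 632.7 CPM). VIM, vimentin, was at 31.8 CPM and 38.5 CPM, LOX was 7.71-fold lower (4.06 to 16.1), and TNC, tenascin C, had 1 read and 310 reads, a ratio of 256 (45.6 to 10100). Stem cell genes had a median of -0.03, which became 0.03 with the TMM scaling undone, with SOX9 3.27-fold and NES, nestin, 2.03-fold higher. Stromal markers (median 0.02) held COL5A1 at 5.72-fold higher (3.25 to 10.8) and VWF at 3.06-fold lower, and in the leukocyte list, with 4 measured members, HBA1 was 8.68-fold lower (3.68 to 25).

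Among the remaining lists, cancer-testis genes had a median of 0.15 with BRDT 5.11-fold higher beside SSX2. Of 12 measured members, 6 were below 0, while 5 were at least 2-fold higher and 1 at least 2-fold lower. The lower one was MAGEA1, named after its values were seen, at 2.57-fold lower (150.4 CPM and 58.47 CPM). Drug transporters and cytochromes P450 had a median of 0.22, with CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, 5.96-fold higher. Of the 16 measured members, 3 were at least 2-fold higher and 2 at least 2-fold lower. These 2 were ABCC4 and CYP4F8, the latter named after its values were seen, with 50 reads in Con and 1 in ENZR, a ratio of Con over ENZR of 60.58 (10.4 to 2440). The long non-coding RNAs had a median of 0.03, with PCAT1 13.9-fold lower. Glycolysis and hypoxia genes (median -0.08, and 0.04 with the TMM scaling undone) held SLC16A3, the lactate exporter, at 12.0-fold lower and CA12, a carbonic anhydrase, at 3.16-fold higher. Lysosome and autophagy genes (median -0.03, and 0.08 with the TMM scaling undone) held NPC1 at 2.62-fold lower and GABARAPL1 at 2.58-fold higher. Immediate early genes (median 0.01) held JUND at 2.12-fold lower and BTG2, of the p53 list too, at 2.37-fold higher.

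Nuclear-encoded genes of oxidative phosphorylation (median -0.25, percentile 4.60) and apoptosis regulators (median 0.21, percentile 97.33) did not stand apart, nor did ribosomal proteins (median -0.10) and ribosome biogenesis genes (median -0.11), whose medians were both 0.01 with the TMM scaling undone. Housekeeping genes stood apart at percentile 98.82 with a median of 0.10 (-0.30 to 0.21), which turned to -0.05 when the median of neighbouring genes was subtracted. POLR2A, the large subunit of RNA polymerase, was 2.25-fold higher, ACTB, beta-actin, 1.28-fold and TBP 1.19-fold. Of the 18 measured housekeeping genes, 10 were above 0 and 8 below. Among the latter, SDHA, named after its values were seen, was 1.985-fold lower. In all, 18 of the 47 lists shown stood apart, where genes drawn at random give about 2.4. That number does not allow for genes of a list that vary together between cultures. The androgen response, cholesterol, fatty acid, ATF4, histone, interferon and semaphorin lists stood apart in every setting tried. The places of the glucocorticoid, basal, mitotic, DNA repair, p53, antigen presentation, NF-kB, WNT, receptor tyrosine kinase, chromatin and housekeeping lists were each lost in 1 or more settings. In turn, the androgen-repressed, neuroendocrine, apoptosis, PI3K, MAPK, drug transporter, G1 regulator, cancer-testis, oxidative phosphorylation, lysosome and immediate early lists each came to stand apart in 1 or more settings.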

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

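With the pseudocount, filter, scaling, abundant genes, repeated symbols, length and GC, neighbours, list membership or matching changed one at a time, the androgen response, cholesterol, fatty acid, ATF4, histone, interferon and semaphorin lists kept their direction and stood apart in every setting. Of the settings, those that subtracted length and GC classes or the neighbours' median, dropped shared members or recomputed TMM were chosen after the data had been seen. Where a value below differs from the main one, the cause was not tested, except that stricter filters leave fewer genes and a larger pseudocount shrinks the ratios of low genes by construction. No gene named reversed its direction in any scaling if it differed by 2-fold or more. This was fixed in advance, since the scalings moved the median log2 ratio of all genes to 0.102 at most. The log2 ratio moved by more than counting error for 69 of 141 named genes with a pseudocount of 5 CPM. It did so for 33 with TMM undone, 10 with upper quartile scaling and 10 with a pseudocount of 0.25 CPM. Without the 10 most abundant genes, it moved for 31 of the named genes left and did not for 109. Depth limits single genes with few reads in one library, whose ratios span wide counting intervals, and no paired analysis was possible because each group has 1 library.

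Counts of genes moved by over 1.5 times in these cases. With a pseudocount of 5 CPM, 447 genes were 2-fold higher and 371 lower (923 and 641 in the report), and 74 were 4-fold higher and 69 lower (263 and 160). With 0.25 CPM, 413 were 4-fold higher. With a mean of 5 CPM or more, 577 were 2-fold and 169 were 4-fold higher. Higher genes made up 59.0% of the genes past 2-fold, 67.1% with TMM undone. With the whole counting interval past the threshold, 782 were 2-fold higher and 523 lower.

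List medians moved as follows. With a pseudocount of 5 CPM, androgen-repressed (0.39), neuroendocrine (-0.22) and PI3K genes (-0.21) came to stand apart, and basal markers (0.13) and receptor tyrosine kinases (-0.11) no longer did. With 0.25 CPM, basal markers (0.55) and WNT genes (0.26) no longer did. Without a filter, androgen-repressed genes (0.89) and apoptosis regulators (0.21) came to stand apart, basal markers (0.06) no longer did, and receptor tyrosine kinases were at 0.0, just across 0 from their value in the report. With a mean of 5 CPM or more, neuroendocrine markers (-0.58) and drug transporters (0.41) came to stand apart, and NF-kB genes (0.34) and receptor tyrosine kinases (-0.18) no longer did.

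With TMM undone, the medians of replication (0.05), oxidative phosphorylation (-0.13), ribosomal protein (0.01), ribosome biogenesis (0.01) and housekeeping genes (0.22) left their intervals. With upper quartile scaling, oxidative phosphorylation (-0.18) and ribosomal proteins (-0.04) did. Without the 10 most abundant genes, oxidative phosphorylation (-0.13), ribosomal proteins (0.01) and ribosome biogenesis (0.0) did, and housekeeping genes (0.22) no longer stood apart.

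With means in place of medians, androgen-repressed genes (0.90), G1 regulators (0.39) and cancer-testis genes (0.80) came to stand apart, and basal markers (0.38), mitotic (-0.28), DNA repair (0.04), p53 (0.18), chromatin (0.16) and housekeeping genes (0.03) no longer did. With length and GC classes subtracted, androgen-repressed genes (0.57), apoptosis regulators (0.26) and PI3K genes (-0.32) came to stand apart, basal markers (0.42), DNA repair (0.11), p53 (0.19), WNT (0.18) and chromatin genes (0.06) no longer did, and ribosomal proteins were at -0.03. With the neighbours' median subtracted, neuroendocrine markers (-0.47), oxidative phosphorylation (-0.28), apoptosis regulators (0.25) and immediate early genes (0.33) came to stand apart, receptor tyrosine kinases (-0.16) no longer did, lysosome genes moved to 0.15 and stood apart, and housekeeping genes reversed to -0.05. With members of 1 list only, glucocorticoid response (-0.31), p53 (0.08), antigen presentation (0.30) and receptor tyrosine kinases (-0.14) no longer stood apart, and MAPK feedback genes came to stand apart at -0.97. With matching in 5 bins, basal markers (percentile 97.48) and housekeeping genes (96.89) no longer stood apart.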

Other observations

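The next ranks of the log2 ratio, among genes with a mean of 10 CPM or more, were looked up after the results had been seen. IGFBP3 and IGFBP5, which bind insulin-like growth factors, stood at 4.61 CPM and 0.245 CPM in Con and at 93.0 CPM and 19.8 CPM in ENZR. The growth factor IGF1 and its receptor IGF1R were lower. CCDC80 (0.245 CPM and 20.6 CPM) and FBLN1 (2.01 CPM and 40.6 CPM) are matrix proteins. CRABP1, a retinoic acid binding protein, had 1 read in Con and 869 in ENZR. SYT4, a synaptotagmin of secretory vesicles, was abundant in ENZR, at 17.4 CPM in Con and 465 CPM in ENZR. BEX1 (0.931 CPM and 49.3 CPM) and RIMS4 (1.72 CPM and 43.8 CPM) are also known from neurons. So are NOVA1 (35.2 CPM and 1.70 CPM) and CADPS2 (35.1 CPM and 1.66 CPM), which were lower in ENZR. PASD1 and SSX2B, 2 more germ cell genes of the X chromosome, were at 46.02 CPM and 41.97 CPM in ENZR.

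Among the lower genes, PRKACB, a catalytic subunit of protein kinase A, was at 765 CPM in Con and 37.5 CPM in ENZR. PARP10, an ADP-ribosyltransferase, was at 85.9 CPM and 3.64 CPM, GGT1, a gamma-glutamyltransferase, at 130 CPM and 9.42 CPM, and KCNMA1, a calcium-activated potassium channel, at 66.1 CPM and 4.65 CPM. TENM1 (27.6 CPM and 0.607 CPM) went the opposite way from its paralog TENM2. TUBA3D and TUBA3E were at 24.5 CPM and 20.8 CPM in Con and at 0.607 CPM and 0.0809 CPM in ENZR, and their near-identical sequences leave the split between them uncertain.

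In the patterns below, the tests of chance placement, of GC content and transcript length on chromosomes and of S phase were chosen after the result was seen, and the settings that subtract length and GC classes or the median of neighbours were added after the data had been seen. The median log2 ratio differed between chromosomes. Genes of chromosome 13 had a median log2 ratio of -0.54 (-0.61 to -0.45, 238 genes), those of chromosome 5 -0.32 and of chromosome 18 -0.30, while chromosome 1 was at 0.17 and chromosome 12 at 0.14. Shuffling genes over chromosomes 1000 times did not give the median of 14 autosomes, which argues against chance placement of genes that vary independently. Neighbouring genes can vary together between cultures, and the shuffle does not allow for that. Subtracting length and GC classes left chromosome 13 at -0.53, which argues against sequence composition as the cause there. On chromosome 13, 83.2% of genes lay below the median of all genes, which restates its low median and tests no explanation. A different number of copies of chromosomes, or of parts of them, in the 2 lines is a candidate explanation that these RNA values do not test. ABCC4 on chromosome 13 was at -3.40 beside a median of -0.53 for its 20 neighbours. A dose shared with these neighbours would account for a part only. A loss confined to ABCC4 would not show in that median.

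Lower histone transcripts could reflect how the libraries were made, the cell cycle or gene dose. The 5 RNAs made without a poly(A) tail that were compared, RMRP, RPPH1, SCARNA9, SCARNA12 and SCARNA17, had a median of -0.02 (-0.37 to 0.44), though with only 22 to 88 reads each. Beside this, the 13 cluster histones, those named HIST, had a median of -1.19 (-1.92 to -0.45), a split made after the result was seen. The comparison does not bear on the variant genes H2AFJ, H2AFZ, H2AFX and H1F0, whose transcripts can carry a poly(A) tail, as some of the cluster histones' can too. The replication list at -0.07 (-0.26 to 0.05) argues against fewer cells in S phase as the whole cause. That holds only as far as its transcripts follow the share of cells in S phase, which was not tested. The mitotic list was lower, at -0.28 (-0.36 to -0.08). The 37 non-histone genes around the chromosome 6 cluster had a median of 0.07 (-0.24 to 0.17). Histone genes less their non-histone neighbours, those on other chromosomes included, stayed at -1.04 (-1.93 to -0.43). Both values argue against a gene dose shared with these neighbours. A loss confined to histone genes would not show in them. A regulated difference between the lines remains as a hypothesis that was not tested.

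The lower androgen response, cholesterol, fatty acid and ATF4 lists kept their places when length and GC classes or the neighbours' median were subtracted. The median closest to 0 among the 4 lists was then -0.52 and -0.51, and in each case no random list was as low as any of the 4. Whether the lower lists belong to the resistant state or to enzalutamide in the medium cannot be told apart, because the series has 0 ENZR libraries from cells grown without the drug. Either may hold for KLK3 and FASN alike.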
